A study of Mus musculus with 8 samples.

How the data were processed

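RNA-seq was made from epidermal cell suspensions of adult mice aged 18 to 25 weeks, killed 4 h after lights on (zeitgeber time ZT4). In the 4 libraries named Bmal1cKO, Cre recombinase under the keratin 14 promoter acted on floxed copies of Bmal1, the gene of a transcription factor of the circadian clock. In the other 4 libraries, named Bmal1WT, the same Cre was present with wild-type Bmal1. Per the labels' protocols, polyA RNA was made into stranded libraries with the TruSeq kit and sequenced as single reads on a NextSeq2000.

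The deposited values are whole-number counts per Ensembl gene, which the authors made from the reads and did not normalise. Per the submitters' processing notes, Trim Galore, STAR 2.7.10a and featureCounts were used with the mouse genome build GRCm38 (mm10). The annotation release, the strand setting and the rule for which genes were listed are not given in the sources used here. The table holds 34070 Ensembl identifiers. GENCODE release M21 on GRCm38 gave symbols and coordinates for 33921 of them, and 149 stayed without a name. Each identifier has at least 1 count in some library, so genes without counts were left out before deposit or were never listed. Total counts ran from 35685261 to 50396156 per library. The mitochondrial gene mt-Atp6 and its near-identical nuclear copy Gm10925 held 1841065 and 1841086 counts over the 8 libraries. Reads that match several places therefore appear to be counted at each of them, and values of paralogs, pseudogenes and overlapping genes are uncertain. Genes that overlap an antisense gene are uncertain as well, since the strand setting is not stated.

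Groups and replicate numbers come from the sample titles. The labels give no batch and no sex, and they do not say which exons of Bmal1 were removed. Sex was read from Xist and from 4 Y-linked genes. In both groups replicates 1 and 3 were female, with Xist at 1146.64 to 1751.661 in counts-per-million (CPM), and replicates 2 and 4 were male. Of the library pairs within a group, none agreed within sampling noise, with a chi-square per degree of freedom of 13.15 to 49.28 over genes with at least 20 counts in the pair. Mitochondrial genes took 2.65 to 4.68% of counts and the 10 most abundant genes 6.82 to 7.74%. Same-numbered libraries of the groups deviated together from their group means, with correlations of 0.33, 0.48, 0.39 and 0.37 across genes. All 4 lay over the minimum of 0.1 set for pairing, so by that rule the numbers pair the samples. The main tests leave this pairing out, and the replicate number as a block is an alternative. Differently numbered libraries of the same sex gave 0.15, 0.17, 0.35 and 0.16, so the rule does not single out the same-numbered pairs. Within a sex these correlations were 0.12 and 0.28. With 2 libraries per sex and group they mirror those of the crossed pairs, so sex accounts for part of the pairing and a shared litter or day cannot be read from it.

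Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (minimum count 10, minimum total count 15), which left 19646 genes. Libraries were scaled by TMM, and the 4 Bmal1cKO and 4 Bmal1WT libraries were compared by the quasi-likelihood F-test (glmQLFit, glmQLFTest, two-sided) with genotype as the only term. P values were adjusted by Benjamini-Hochberg over all genes tested, and a gene was called at an adjusted p under 0.05. Values per library are CPM on TMM-scaled library sizes. Means are given with the standard deviation (SD) over 4 libraries, and log2 fold changes, Bmal1cKO over Bmal1WT, with their standard error (SE). The labels do not say that each library comes from a separate animal, so the p values measure the spread between these libraries, which may be technical in part.

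A total of 33 gene lists, with 566 members matched to an identifier, was fixed, 9 of them as main lists. They cover clock E-box targets, clock positive limb and REV-ERB-repressed genes, the YAP/TAZ target signature, AP-1 subunits, keratinocyte IL-17 and alarmin genes, NF-kB target genes, the type I interferon response, keratinocyte differentiation, and stress keratins with regenerative keratinocyte genes. The further lists hold Hippo-YAP pathway components, basal keratinocyte genes, S phase, G2 and M phase, oxidative phosphorylation, glycolysis and hypoxia, NRF2 and antioxidant, p53 target, cholesterol synthesis, barrier lipid, glucocorticoid, TGF-beta and BMP, Wnt, and immediate-early and dissociation stress genes. Other lists hold markers of Langerhans cells, epidermal T cells, macrophages and neutrophils, melanocytes, dermal fibroblasts, endothelial and mural cells, skeletal muscle with adipocytes and red cells, the bulge, growing hair follicles, and sebaceous glands. Further members, Il36a, Defb3, Saa3, Rigi, Lce3b, Sprr2k, Sprr3, Aldoa, Retnlg, Ngp and Krt85, were not matched to a single identifier, and 500 different members were tested. Lists were tested against all other genes with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation between genes of 0.01, Benjamini-Hochberg adjusted over the 33 lists. Camera with a correlation estimated per list and fry, which tests whether the members of a list move on balance in 1 direction, stand beside it. A list score is the mean log2 CPM of the members in a library minus the mean over Bmal1WT. Scores were compared by a two-sided exact permutation test over the 35 splits of 8 libraries, whose smallest p is 0.029.

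The named genes are Bmal1, every tested member of the clock lists, and the 12 highest and 12 lowest fold changes among called genes. The last had an average log2 CPM of at least 0 and no overlap between the groups, and predicted or unnamed gene models were left out. From each other list up to 4 members with the smallest p were eligible, printed in order of p. Some genes that this rule names are not reported here. The tests, lists, this rule and the alternatives were fixed before the data were examined, except those said to be chosen later. The alternatives were DESeq2 size factors, upper quartile scaling, library size only, no count filter, a filter of at least 1 CPM in at least 4 libraries, each library left out, the replicate number as a block, and sex as a covariate. DESeq2 1.42.0, limma voom without and with sample quality weights, robust dispersions, an adjusted p under 0.01 and a minimum fold of 1.5 were run too. Fits on female or on male libraries alone, and a count without the genes within 40 Mb of Bmal1 on chromosome 7, were chosen after seeing the data. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

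The test was tried on simulated counts drawn from the means and library sizes of these libraries, with 200 changed genes. The spread was taken from its trend over abundance, so genes of like abundance shared a common spread, and genes were drawn independently. The recovered shares below hold for that setting and may differ from those in the data, where the spread differs between genes. Without a sex effect, run on 19415 genes, it recovered 47% of genes changed by a log2 of 0.5, 89.2% at 1 and 100% at 2, with 11 false calls of 165. When the simulated counts carried a sex effect (19414 genes), the genotype-only fit recovered 18.5%, 64.6% and 84.6%, with 0 false calls of 109, and the fit with sex as a covariate 41.5%, 80% and 98.5%, with 4 of 147. Floors for genes with 0 counts are 3 counts over a group and cover counting error only, since the reads carry no molecular identifiers.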

Results

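Gene expression was compared between the epidermis of Bmal1cKO mice, in which keratin 14-driven Cre acts on floxed Bmal1, and that of Bmal1WT mice with the same Cre. The comparison asks which epidermal transcripts differ in the absence of keratinocyte BMAL1 at ZT4, in a series concerned with BMAL1, YAP and inflammation. Each group held 4 libraries. Total counts were 36353165, 40398749, 50396156 and 45772646 in Bmal1WT replicates 1 to 4 and 38077351, 38656738, 35685261 and 38032762 in Bmal1cKO replicates 1 to 4. The first principal component of the 500 most variable genes took 52.1% of their variance and separated the male from the female libraries, and each group held 2 of either sex. The second, with 19.6%, separated the genotypes.

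Bmal1 itself (symbol Arntl, ENSMUSG00000055116, GRCm38 chromosome 7, 113207465 to 113314126, plus strand) was counted at 46.1, 42, 49.1 and 48.7 CPM in Bmal1WT replicates 1 to 4. Bmal1cKO replicates 1 to 4 had 32, 34.4, 37.6 and 30.7 CPM, so the 4 values of the groups did not overlap. The mean was 46.5 ± 3.29 CPM in Bmal1WT and 33.7 ± 3.01 CPM in Bmal1cKO (SD, n = 4), a log2 fold change of -0.47 ± 0.08 (SE) with an edgeR quasi-likelihood adjusted p = 0.0611. For the Bmal1 transcript the adjusted p was 0.0358 with the replicate block, and over the alternatives it ran from 5.96e-05 with DESeq2 to 0.693 in the 4 female libraries alone. The counts are sums over the whole gene and may include exons outside the removed part.

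The called genes included members of the clock lists. Nr1d1, which encodes the repressor REV-ERB alpha (ENSMUSG00000020889, chromosome 11, 98767932 to 98775333), fell from 118 ± 17.1 to 2.58 ± 0.567 CPM (SD, n = 4), 45.7-fold lower, with a log2 fold change of -5.51 ± 0.17 (SE, edgeR adjusted p = 9.09e-07). Its paralog Nr1d2 fell from 111 ± 10.1 to 17.3 ± 2.77 CPM (-2.69 ± 0.12, edgeR adjusted p = 5.66e-06). Dbp, a PAR-bZIP output factor of the clock, fell from 28.4 ± 7.19 to 6.15 ± 0.536 CPM (-2.21 ± 0.18, edgeR adjusted p = 0.000487). The period gene Per3 fell from 34.7 ± 6.27 to 12.8 ± 0.883 CPM (-1.45 ± 0.13, edgeR adjusted p = 0.00111). Nr1d1, Dbp and Per3 overlap the expressed genes Thra, Sphk2 and Camta1, so their remaining counts are uncertain.

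The cryptochrome gene Cry1, a repressor within the clock, rose from 9.52 ± 2.49 to 65.9 ± 7.07 CPM, with a log2 fold change of 2.79 ± 0.17 (edgeR adjusted p = 6e-05). Npas2, the paralog of Clock and a partner of BMAL1, rose from 14.8 ± 2.15 to 48.6 ± 3.74 CPM (1.72 ± 0.11, edgeR adjusted p = 6.94e-05). Per2 was at 4.86 ± 1.65 and 17.7 ± 9.44 CPM, without overlap of the groups, and missed the threshold (1.86 ± 0.37, edgeR adjusted p = 0.13, 0.00303 with the replicate block, 0.00303 to 0.664 over the alternatives). Nfil3, a repressor of Dbp target sites, was at 8.06 ± 3.17 and 13.6 ± 1.99 CPM (0.75 ± 0.23, edgeR adjusted p = 0.403, 0.0405 with the replicate block, 0.0212 without Bmal1WT replicate 4 to 0.708 over the alternatives).

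**Figure D1:**
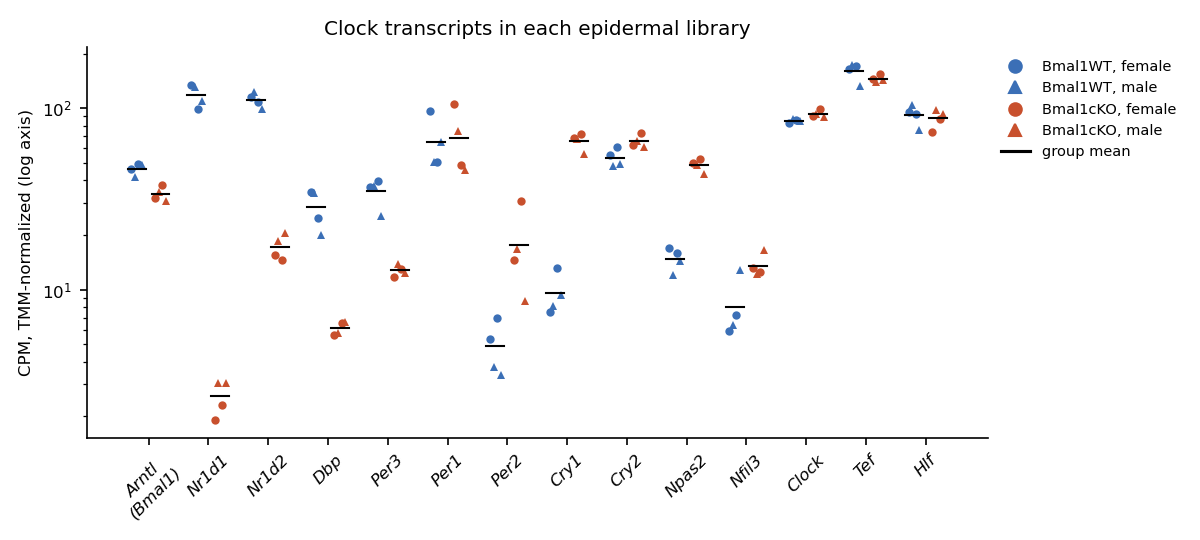
Expression of Bmal1 and clock genes in each epidermal library, in CPM on a log axis, with circles for female and triangles for male libraries and bars for the group means. Nr1d1 lay at 118 CPM in Bmal1WT and 2.58 CPM in Bmal1cKO, whereas Cry1 lay at 9.52 and 65.9 CPM.

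Of the 17 clock E-box targets, the genes that CLOCK and BMAL1 drive in many tissues, 2 rose and 4 fell over all genes tested, and 4 were higher and 5 lower when adjusted over the list alone. The remaining members missed the threshold over all genes. Cry2 had a log2 fold change of 0.30 ± 0.09 (edgeR adjusted p = 0.369), Bhlhe41 -1.10 ± 0.36 (0.43), Ciart -0.61 (0.715), Tef -0.14 (0.737) and Hlf -0.06 (0.936). The values were 0.07 ± 0.29 for Per1 (edgeR adjusted p = 0.979), -0.28 for Bhlhe40 (0.926), -0.13 for Wee1 (0.93), 0.03 for Usp2 (0.979) and 0.07 for Nampt (0.894). As a list with members in both directions, it had a median log2 fold change of -0.13 and a camera adjusted p = 0.144 (0.822 with an estimated correlation). It passed without Bmal1WT replicate 4 (0.0182), and the range over the alternatives was 0.0182 to 0.822. The scores of the list did not overlap between the groups (exact permutation p = 0.029, the smallest possible, n = 4, adjusted over the lists 0.236). When fry counted members moving in either direction, its adjusted p was 3.02e-06.

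In the list of 6 positive limb and REV-ERB-repressed genes, 1 rose over all genes, and 3 were higher and 1 lower when adjusted over the list alone. Rora, which encodes a ROR activator, had a log2 fold change of -0.34 ± 0.12 (edgeR adjusted p = 0.453), Clock 0.12 ± 0.05 (0.519), and Arntl2 0.06 (0.936). Camera called the list higher, with a median of 0.09 (adjusted p = 0.0236), against an adjusted p = 0.396 with an estimated correlation and 0.0583 with the replicate block. The call was lost without Bmal1WT replicate 1 (0.0518) and without Bmal1cKO replicate 3 (0.0831), and the adjusted p ran from 0.00557 to 0.396 over the alternatives.

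Over all genes, edgeR called 34 of 19646, 17 higher and 17 lower in Bmal1cKO, and 30 of them differed at least 1.5-fold. At an unadjusted p under 0.05 there were 1631 genes, where 982 would fall by chance. In all 34 the 4 values of the groups did not overlap, as in 1012 tested genes (5.2%, chance gives 2.86%). With the replicate block 152 genes were called, 102 higher and 50 lower, and with sex as a covariate 119, and each set held all 34. Splitting the libraries by sex instead of genotype gave 163 genes. Left-out fits called 23 to 32 genes, and 21 of the 34 were called in all 8.

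Among the genes that fell, Arrb1, which encodes the receptor adaptor beta-arrestin, went from 104 ± 5.46 to 34.4 ± 1.75 CPM (SD, n = 4, log2 fold change -1.59 ± 0.06, edgeR adjusted p = 1.43e-06). Cdc25b, a phosphatase that promotes entry into mitosis, fell from 56.5 ± 4.63 to 24 ± 1.64 CPM (-1.24 ± 0.07, edgeR adjusted p = 6e-05), and it overlaps Spef1 on the other strand. Ngfr, a neurotrophin receptor gene, fell from 23.8 ± 3.22 to 7.54 ± 0.86 CPM (-1.65 ± 0.12, edgeR adjusted p = 0.00019). The sulfatase gene Arsi fell from 6.09 ± 0.742 to 1.02 ± 0.21 CPM (-2.57 ± 0.17, edgeR adjusted p = 9.73e-05). Trim12a fell from 20.3 ± 3.65 to 2.33 ± 0.418 CPM (-3.12 ± 0.17, edgeR adjusted p = 4.24e-05), and its neighbour Trim34a from 12.6 ± 2.82 to 5.43 ± 0.185 CPM (-1.22 ± 0.16, edgeR adjusted p = 0.0176). Both belong to a family of close paralogs and are uncertain, as is the processed pseudogene AC170187.1, with -2.60 ± 0.16 (edgeR adjusted p = 6e-05). Rsad1 fell from 11.1 ± 0.971 to 5.42 ± 1.11 CPM (-1.03 ± 0.14, edgeR adjusted p = 0.0257). In the left-out fits Trim34a kept its call only without Bmal1WT replicate 3 (0.0386) or 4 (0.000262), with up to 0.0869 otherwise. Rsad1 kept its call in these fits only without Bmal1WT replicate 3 (0.0386), Bmal1cKO replicate 3 (0.044) or 4 (0.0142), with up to 0.103 otherwise.

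Among the genes that rose, Slc38a4, an amino acid transporter gene, went from 7.29 ± 1.65 to 31.5 ± 6.7 CPM (SD, n = 4, log2 fold change 2.11 ± 0.19, edgeR adjusted p = 0.000989). Il18r1, a receptor subunit for the inflammatory cytokine IL-18, rose from 22.9 ± 1.09 to 43.2 ± 1.95 CPM (0.91 ± 0.06, edgeR adjusted p = 6.94e-05). Frem2, an extracellular matrix gene of the basement membrane zone, rose from 76.4 ± 4.87 to 104 ± 3.22 CPM (0.45 ± 0.06, edgeR adjusted p = 0.013). The cadherin gene Cdh13 rose from 100 ± 3.06 to 131 ± 5.66 CPM (0.38 ± 0.05, edgeR adjusted p = 0.015). Frem2 lost its call without Bmal1cKO replicate 2 (0.0649), and Cdh13 without Bmal1WT replicate 3 (0.0591) or Bmal1cKO replicate 2 (0.0794).

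The other named genes that rose were called in 1 or 2 of the 8 left-out fits. Atp6v1g3, a proton pump subunit gene, went from 0.864 ± 0.285 to 5.67 ± 2.45 CPM (2.7 ± 0.37, edgeR adjusted p = 0.0232), Gpha2 from 7.94 ± 2.69 to 23.7 ± 2.31 CPM (1.57 ± 0.21, 0.022), Ttc9 from 32.4 ± 8.09 to 70 ± 7.98 CPM (1.11 ± 0.16, 0.0319) and Fah, a tyrosine breakdown enzyme gene, from 8.67 ± 0.974 to 17.4 ± 3.13 CPM (1.01 ± 0.14, 0.022). Gpha2 overlaps Ppp2r5b on the other strand. Atp6v1g3 was called in the left-out fits only without Bmal1WT replicate 3 (0.0386) or Bmal1cKO replicate 1 (0.00702), with an adjusted p of up to 0.0921 otherwise. Gpha2 was called only without Bmal1WT replicate 3 (0.00862) or 4 (0.0212), with up to 0.0745 otherwise. Ttc9 was called only without Bmal1WT replicate 3 (0.00185), with up to 0.103 otherwise, and Fah only without Bmal1cKO replicate 1 (0.0235) or 2 (0.0383), with up to 0.0819 otherwise.

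Of the 34 called genes, 9 lay within 40 Mb of Bmal1 on chromosome 7, 4 higher and 5 lower, a place examined after the calls were seen. All 9 lay at lower coordinates than Bmal1. They make up 1.23% of the 732 genes tested there, against 0.132% of the genes elsewhere (one-sided Fisher exact p = 2.99e-06). Arrb1 starts at 99535466, Trim34a at 104244457, Trim12a at 104299894 and Fah at 84585159. Outside the naming rule, Trim30d fell from 1.14 ± 0.533 to 0.0727 ± 0.065 CPM (SD, n = 4, -3.91 ± 0.59, edgeR adjusted p = 0.0419), a call kept in the left-out fits only without Bmal1WT replicate 4 (0.0416), with up to 0.171 otherwise. The long noncoding RNA Gm35082 (100675088 to 100677760) had 0 counts in the Bmal1WT libraries and 307 in Bmal1cKO (2.04 CPM), at least 117-fold higher against a floor of 3 counts over the group.

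**Figure D2:**
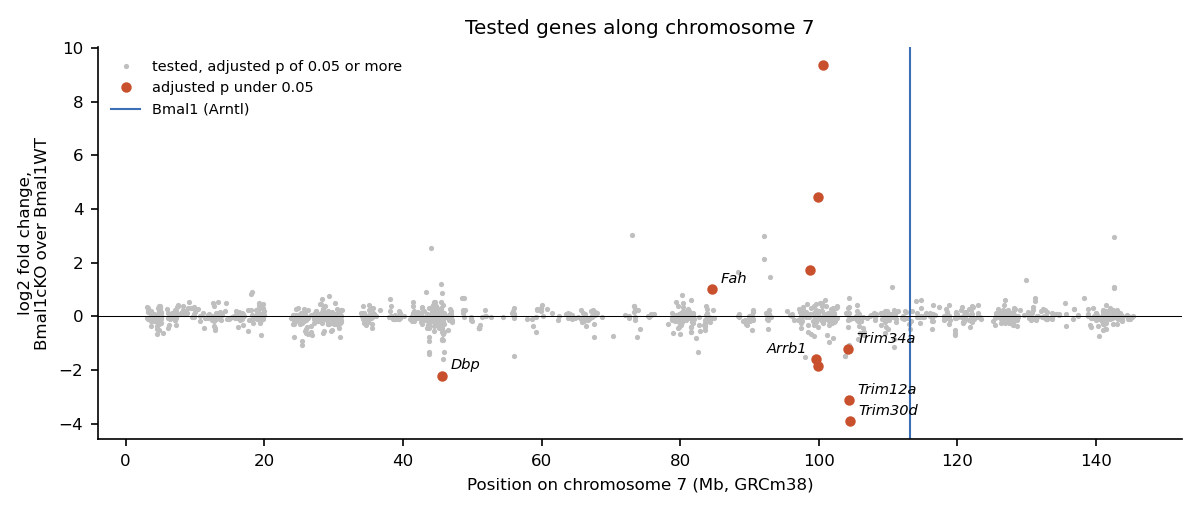
Log2 fold change (Bmal1cKO over Bmal1WT) of the tested genes along chromosome 7 in Mb of GRCm38, with called genes in red and the position of Bmal1 as a vertical line. Of the called genes, 9 lie within 40 Mb of Bmal1, and Dbp lies farther away at 45705088.

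Basal and differentiated keratinocyte genes lay on opposite sides. All 26 differentiation genes, which build the spinous, granular and cornified layers, had negative fold changes, with a median log2 of -0.68. Flg, which encodes filaggrin, was at 231 ± 102 CPM in Bmal1WT and 64 ± 22.8 CPM in Bmal1cKO (-1.85 ± 0.35, edgeR adjusted p = 0.103, 0.0386 with sex as a covariate, 0.00136 with DESeq2 to 0.689 in female libraries alone over the alternatives). It overlaps Rplp0-ps1 on the same strand (70410 counts against 49773 of Flg), so its counts are uncertain. Cnfn was at 13.2 and 6.95 CPM (-0.92 ± 0.22, edgeR adjusted p = 0.232) and the desquamation protease Klk7 at 163 ± 38 and 86.2 ± 28.9 CPM (-0.92 ± 0.25, 0.295). Of the 16 basal genes 15 had positive fold changes, with a median of 0.16. Col7a1, which encodes the anchoring fibril collagen, was at 333 ± 35.1 and 452 ± 35.9 CPM (0.44 ± 0.09, edgeR adjusted p = 0.138).

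Over all genes edgeR called 0 members of either list, and with the replicate block 1 differentiation gene, lower, and 1 basal gene, higher. For differentiation, 8 members had an unadjusted p under 0.05, DESeq2 called 2, voom 0, and 3 were lower when adjusted over the list alone. The basal genes gave 6, 4 and 0 by the same measures, with 5 higher when adjusted over the list alone. Camera called the differentiation list lower (adjusted p = 3.46e-08, adjusted p = 0.447 with an estimated correlation, 1.31e-09 to 0.447 over the alternatives) and the basal list higher (adjusted p = 7.12e-08, adjusted p = 0.313 with an estimated correlation, 3.86e-08 to 0.313 over the alternatives). Both calls held in each left-out fit. Their scores did not overlap between the groups (exact permutation p = 0.029 for each, the smallest possible, n = 4, adjusted over the lists 0.236). The 16 barrier lipid genes had a median of -0.15, with Aloxe3, a lipoxygenase gene, at 37.5 ± 7.52 and 25.6 ± 3.39 CPM (-0.55 ± 0.15, edgeR adjusted p = 0.303). Of them 0 passed in edgeR and voom, 1 in DESeq2, 6 at an unadjusted p under 0.05, and 3 were lower when adjusted over the list alone. Camera called this list lower (adjusted p = 0.000474, adjusted p = 0.726 with an estimated correlation, 2.37e-05 to 0.726 over the alternatives), and the call was lost without Bmal1cKO replicate 3 (0.0539).

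Camera called 11 of the 33 lists, 6 higher and 5 lower, and 0 with an estimated correlation (3 at an unadjusted p under 0.05), while fry called 2, the basal and the positive limb lists. For the scores of called lists the exact permutation p was 0.029 for the positive limb, 0.257 for NF-kB, 0.314 for interferon, 0.486 for glycolysis, 0.086 for barrier lipids, 0.057 for muscle, adipocyte and red cells and 0.257 for growing hair. Of the 35 splits of the libraries, 19 gave at least 11 called lists, so these calls do not stand apart from other splits of the same libraries. The directions given for the clock, keratinocyte and other lists therefore describe these libraries only.

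**Figure D3:**
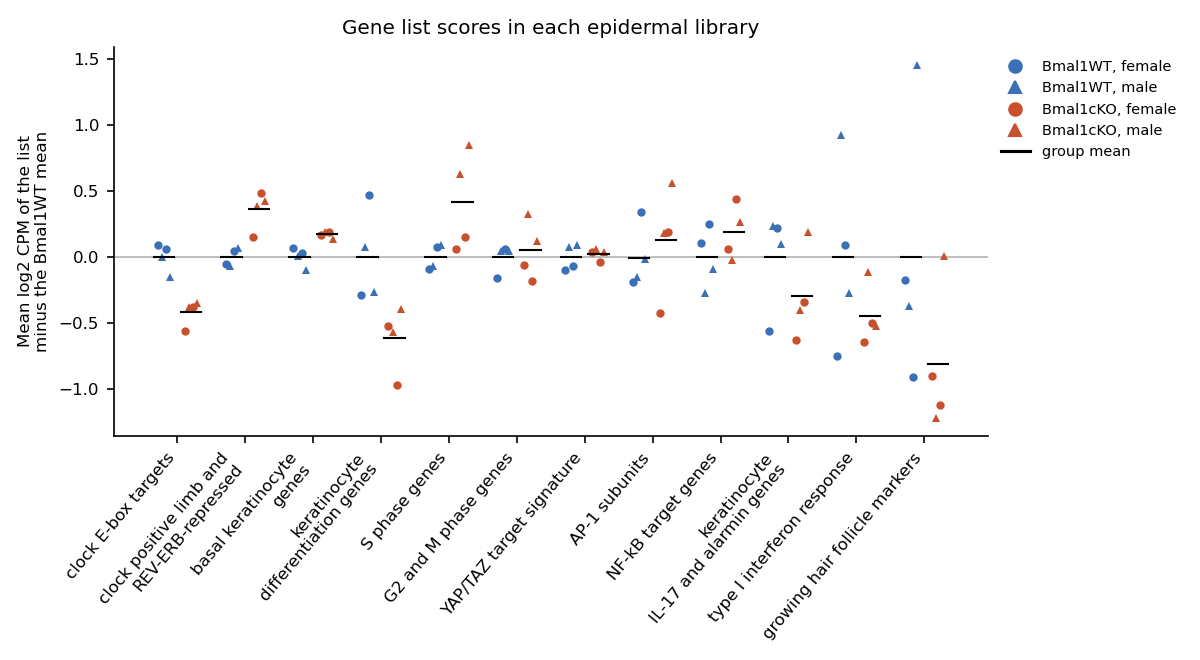
Mean log2 CPM of the members of 12 gene lists in each library minus the Bmal1WT mean, with circles for female and triangles for male libraries and bars for the group means. The differentiation and basal scores do not overlap between the genotypes, and the S phase score of the 2 male Bmal1cKO libraries lies at 0.63 and 0.85.

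The YAP/TAZ target signature, 20 genes that YAP and TAZ induce in many cells, had a median log2 fold change of 0.09. Its member with the smallest p, Amotl2, a YAP-binding regulator, was at 77.6 ± 3.77 CPM in Bmal1WT and 101 ± 12.5 CPM in Bmal1cKO (SD, n = 4, 0.38 ± 0.09, edgeR adjusted p = 0.181). Fjx1 was at 7.25 and 10.2 CPM (0.50 ± 0.13, edgeR adjusted p = 0.256) and Ccdc80 at 1.35 ± 1.54 and 0.199 ± 0.112 CPM (-2.73 ± 0.80, 0.366). Over all genes edgeR called 0 members, against 6 at an unadjusted p under 0.05, 3 by DESeq2 and 0 by voom, and 3 were higher and 1 lower when adjusted over the list alone. With the replicate block edgeR called 1 member, which was higher. Camera called the list higher (adjusted p = 0.0145, adjusted p = 0.313 with an estimated correlation, 0.00335 to 0.313 over the alternatives), but its score difference was only 0.02 (exact permutation p = 0.743, n = 4), 0.08 between the female and -0.03 between the male libraries. The 20 Hippo-YAP pathway components had a median of -0.02, opposite to the direction camera gave (adjusted p = 0.987). EdgeR, DESeq2, voom and the list alone called 0 of them, and 2 had an unadjusted p under 0.05.

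Of the AP-1 subunits Fosb was at 1430 ± 216 and 2020 ± 793 CPM (0.50 ± 0.27, edgeR adjusted p = 0.689), Jund at 0.37 on the log2 scale (0.733) and Jun at 1530 ± 379 and 1980 ± 553 CPM (0.37 ± 0.24, 0.748). The 11 subunits had a median of 0.23 (camera adjusted p = 0.258), with 0 calls by edgeR, DESeq2 or voom, 0 when adjusted over the list alone and 0 at an unadjusted p under 0.05. The list passed without Bmal1WT replicate 3 (0.0482) or Bmal1cKO replicate 1 (0.0025), and the range over the alternatives was 0.0016 to 0.947.

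In the keratinocyte IL-17 and alarmin list, Ccl20, a chemokine for IL-17-producing cells, was at 1.02 ± 0.466 and 2.66 ± 0.415 CPM (1.36 ± 0.28, edgeR adjusted p = 0.141, 0.0334 with the replicate block, 0.0106 without Bmal1WT replicate 3, 0.00151 to 0.839 over the alternatives). The cytokine gene Il1f8, now Il36b, was at 1.52 ± 1.05 and 0.322 ± 0.127 CPM (-2.22 ± 0.50, edgeR adjusted p = 0.181). The 12 members had a median of -0.40 (camera adjusted p = 0.566). EdgeR and voom called 0, DESeq2 2, 3 had an unadjusted p under 0.05, and 1 was higher and 1 lower when adjusted over the list alone.

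Among 15 NF-kB target genes, Icam1, a leukocyte adhesion molecule, was at 32.9 ± 5.08 and 49.9 ± 8.64 CPM (0.60 ± 0.14, edgeR adjusted p = 0.189) and Relb at 23.9 and 29.5 CPM (0.30 ± 0.09, 0.404). Camera called the list higher (median 0.11, adjusted p = 0.00345, adjusted p = 0.689 with an estimated correlation, 0.000289 to 0.689 over the alternatives), and the call was lost without Bmal1cKO replicate 3 (0.0539). EdgeR and voom called 0 members, DESeq2 1, 3 had an unadjusted p under 0.05, and 1 was higher when adjusted over the list alone. All 20 interferon response genes had negative fold changes, with a median of -0.64. The antiviral effectors Bst2 (-0.68 ± 0.26, edgeR adjusted p = 0.52), Ifit1 (-1.52 ± 0.73, 0.629) and Oas3 (-1.53 ± 0.74, 0.635) missed the threshold. Camera called this list lower (adjusted p = 0.00145, adjusted p = 0.907 with an estimated correlation, 9.08e-08 to 0.907 over the alternatives). The call was lost without Bmal1WT replicate 2 (0.238), which had an Oas3 level of 9.59 CPM against at most 1.79 CPM in the other Bmal1WT libraries. EdgeR, DESeq2, voom and the list alone called 0 interferon genes, and 1 had an unadjusted p under 0.05.

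All 20 S phase genes, which act in DNA replication, had positive fold changes, with a median of 0.49. Ccne2, which encodes cyclin E2, was at 4.72 ± 0.274 and 7.17 ± 1.13 CPM (SD, n = 4, 0.60 ± 0.13, edgeR adjusted p = 0.147), and Rrm2, a ribonucleotide reductase subunit gene, at 19.4 ± 1.3 and 27 ± 5.85 CPM (0.48 ± 0.14, 0.368). EdgeR and voom called 0, DESeq2 1, 15 had an unadjusted p under 0.05, and 13 were higher when adjusted over the list alone. Camera called the list higher (adjusted p = 5.21e-11, adjusted p = 0.632 with an estimated correlation, 3.46e-17 to 0.632 over the alternatives), and the call held in each left-out fit. The score difference was 0.11 between the female and 0.73 between the male libraries, and over both it was 0.42 (exact permutation p = 0.086, n = 4). For the 20 G2 and M phase genes the median was 0.07 (camera adjusted p = 0.274), with 2 at an unadjusted p under 0.05 and 0 called by edgeR, DESeq2, voom or over the list alone.

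The 19 glycolysis and hypoxia genes had a median of 0.12 and were called higher by camera (adjusted p = 0.0248, adjusted p = 0.941 with an estimated correlation, 0.0521 with the replicate block, 3.01e-05 to 0.947 over the alternatives). This call was lost without Bmal1WT replicate 1 (0.0819) or 3 (0.14) and without Bmal1cKO replicate 3 (0.643) or 4 (0.199). EdgeR, DESeq2, voom and the list alone called 0 of them, against 2 at an unadjusted p under 0.05. The other metabolic and signalling lists missed the threshold, with camera adjusted p = 0.281 for oxidative phosphorylation, 0.864 for NRF2 and antioxidant, 0.48 for p53 target, 0.849 for cholesterol synthesis and 0.849 for glucocorticoid genes. For TGF-beta and BMP targets it was 0.445, for Wnt targets 0.83, for immediate-early and dissociation stress genes 0.467 and for stress keratin and regenerative keratinocyte genes 0.319. EdgeR, DESeq2, voom and the list alone called 0 members of these 9 lists. Unadjusted p under 0.05 was reached by 1 gene of oxidative phosphorylation, 5 of the NRF2 and 3 of the TGF-beta list, and by 0 of the other 6 lists. For the NRF2 list the mean (-0.03) was opposite to the median (0.02) and to the direction of camera, and for the glucocorticoid list the median (0.01) was opposite to the mean (-0.01) and to camera.

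Markers of growing hair follicles varied widely between libraries of a group. Dlx3 was at 7.53 and 4.91 CPM (-0.62 ± 0.22, edgeR adjusted p = 0.463) and the hair keratin gene Krt33a at 0.689 and 0.231 CPM (-1.56 ± 0.60, 0.52). Their list of 16 had a median of -1.26, with 3 members at an unadjusted p under 0.05 and 0 called by edgeR, DESeq2, voom or over the list alone. Camera called it lower (adjusted p = 0.000984, adjusted p = 0.822 with an estimated correlation, 3.7e-07 to 0.822 over the alternatives), and the call was lost without Bmal1WT replicate 4 (0.0804), whose score was 1.46 against at most -0.17 in the other Bmal1WT libraries. Of 5 skeletal muscle, adipocyte and red cell markers, the globin gene Hbb-bt was at 1.05 ± 0.195 and 0.377 ± 0.181 CPM (-1.49 ± 0.31, edgeR adjusted p = 0.149, 0.0474 without Bmal1cKO replicate 3, 0.0127 to 0.839 over the alternatives). Camera called that list lower (median -0.08, adjusted p = 0.022, adjusted p = 0.447 with an estimated correlation, 0.0033 to 0.447 over the alternatives), and the call was lost without Bmal1cKO replicate 1 (0.0514). EdgeR and voom called 0 members, DESeq2 2, 2 had an unadjusted p under 0.05, and 2 were lower when adjusted over the list alone.

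The remaining cell type lists missed the threshold. Among 16 epidermal T cell markers Thy1 was at 48.3 ± 12.2 and 70.3 ± 9.64 CPM (0.54 ± 0.17, edgeR adjusted p = 0.421, 0.0226 with the replicate block, 0.0226 to 0.794 over the alternatives), while 15 of the 16 had negative fold changes. Camera gave this list an adjusted p = 0.0594, and 0.00241, lower, with the replicate block (0.722 with the block and an estimated correlation), with a range of 2.4e-06 to 0.947 over the alternatives. It passed without Bmal1WT replicate 2 (0.000305) or Bmal1cKO replicate 3 (2.4e-06). The 15 Langerhans cell markers had a camera adjusted p = 0.305, and 0.00685, higher, with the replicate block (0.722 with the block and an estimated correlation), with a range of 0.0046 to 0.952, and passed without Bmal1WT replicate 1 (0.0439) or 3 (0.0156) or Bmal1cKO replicate 2 (0.0046). H2-DMb1, H2-DMa and Cd74, genes of antigen presentation, had edgeR adjusted p values of 0.916, 0.922 and 0.927. Camera adjusted p was 0.849 for macrophages and neutrophils, 0.305 for melanocytes, 0.469 for endothelial and mural cells, 0.488 for the bulge and 0.469 for sebaceous glands. Dermal fibroblast markers had a median of -0.44 against a direction of up in camera (adjusted p = 0.913), with Sparc at 57.6 and 84.3 CPM (0.55 ± 0.16, edgeR adjusted p = 0.369), Col6a1 at 0.49 ± 0.15 on the log2 scale (0.404), Dcn at -1.45 ± 0.82 (0.712) and Col1a1 at -1.55 ± 0.96 (0.743). EdgeR, DESeq2 and voom called 0 members of these 8 lists, and 2 fibroblast markers were higher when adjusted over the list alone. Unadjusted p under 0.05 was reached by 2 fibroblast and 1 T cell marker, and by 0 of the other 6 lists.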

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

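Of the tests in this part, the splits of the libraries for the gene lists, with sex as a covariate and with the replicate block, and the count on chromosome 7 without Trim genes were chosen before their results were seen, and the others after.

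The first pattern is the place of the called genes around Bmal1 on chromosome 7. On the other chromosomes, 0 percent of 18114 tested genes had as many called genes within 40 Mb (the highest had 4), and 8 of the 9 lie within 20 Mb of Bmal1. Within 10 Mb, 2.501% of those genes had as many as the 3 near Bmal1. These shares argue against chance clustering, but the windows overlap widely and stand for far fewer independent places than genes. All 9 lie on the side of lower coordinates, among 348 genes tested there, and 0 among 384 on the other side, and the 3 within 10 Mb are all Trim genes. Without the Trim genes, whose paralogs share reads, 6 called genes stayed among 720 (one-sided Fisher exact p = 0.000807), which argues against reads shared between these paralogs as the whole cause. With the replicate block 21 genes were called there (Fisher exact p = 2.04e-07), 17 on the side of lower coordinates and 4 on the other. Sequence differences linked to the targeted allele, such as a flanking stretch from another mouse strain, may explain the 9 calls and cannot be told apart from a loss of BMAL1, because the linked region and the genotype go together in every library. An excess on both sides of Bmal1, expected of such a stretch, was not seen in the 9 calls, but how far it would reach on either side is not known.

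The second pattern is that Bmal1cKO kept 72.4% of Bmal1 counts (66.1 to 80.8% in single libraries, each against the Bmal1WT mean) but 2.18% of Nr1d1 counts. If cells with an intact Bmal1 allele, in or outside the keratinocytes, gave the remaining Bmal1 counts, Nr1d1 should stay at a like share, and the highest share left in a library was 2.59% of the Bmal1WT mean. That argues against intact cells as the whole cause, as far as such cells carry both transcripts in the Bmal1WT ratio. A mislabelled sample is argued against by 0 libraries with Nr1d1 on the side of the other group. A transcript of the recombined allele that is still counted may account for the 72.4%, and this stays open without values per exon.

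The third pattern is that S phase genes were higher in Bmal1cKO, with a score difference of 0.73 (SE 0.14) between male and 0.11 between female libraries. More cycling cells at every stage would raise G2 and M phase genes alike, but the S minus G2 and M score was higher in Bmal1cKO by 0.37 (exact permutation p = 0.029, n = 4, the smallest possible). Over the same-numbered pairs its exact sign-flip p was 0.125. Between male libraries the S minus G2 and M score was higher by 0.56, and the G2 and M score by 0.18 (SE 0.11). The SE of the 0.56 was 0.23 between unpaired libraries, 0.13 over the pairs as numbered and 0.3 over the male pairs crossed. The bound of 2 SE lies above 0 except over the crossed pairs, and the score was formed after its 2 parts were seen. More cycling cells at every stage therefore cannot be told apart. More growing hair follicles would raise their score, but it was lower in Bmal1cKO in all 4 same-numbered pairs (by 0.21 to 1.45, mean -0.81, SE 0.26 over the pairs, exact sign-flip p = 0.125, the smallest possible with 4 pairs). Without pairing, the exact permutation p of the growing hair score was 0.257. The male difference was -1.15, with an SE of 0.3 over the pairs as numbered, 1.53 over the male pairs crossed and 1.1 between unpaired libraries. More growing follicles therefore cannot be told apart, because the bound of 2 SE lies below 0 only if the replicate numbers pair the samples, which their correlations do not single out. A genotype effect that differs by sex stays open, with an unadjusted camera interaction p of 0.0585 under an estimated correlation (0.935 adjusted over the lists).

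The number of called genes was weighed against other splits. Of the 35 splits of the 8 libraries 2 gave at least 34 genes, so chance is not excluded by that count, and the other split is that of female against male libraries with 163 genes, a structure of the samples. With sex as a covariate 1 of 34 splits reached the 119 genes of the real split (the highest other gave 6). Many of these splits divide the sexes unevenly, unlike the real one. Those that divide them evenly are too few for a share under 0.05, so chance is not excluded there. With the replicate block 1 of the 8 splits that part all pairs reached 152 genes (highest other 0), and 8 splits are too few for a share under 0.05. For the lists 19 of 35 splits reached 11 (highest other 18), so chance is not excluded.

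Effects of genotype were compared between the sexes by the genotype-by-sex interaction, with camera at the preset correlation and Benjamini-Hochberg adjustment over the lists. The adjusted p was 0.0289 for clock E-box targets (score difference -0.55 in females and -0.29 in males), 0.0245 for AP-1 subunits (-0.19 and 0.45), 1.66e-15 for S phase (0.11 and 0.73) and 0.000213 for G2 and M phase genes (-0.07 and 0.18). It was 6.52e-09 for cholesterol synthesis (-0.20 and 0.22), 0.0245 for Langerhans cell markers (-0.02 and 0.47) and 0.018 for sebaceous gland markers (-0.24 and 0.39). All 7 are lost with an estimated correlation (adjusted p 0.935 to 0.939). For single genes edgeR called 1 interaction, Krt2, a keratin of the upper epidermis (log2 -3.78, adjusted p = 0.00716, 1304 genes at an unadjusted p under 0.05).

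In 19 of 230 groups of 4 values (8.3%) 1 library stood apart, where chance gives about 1 in 20. The gap to the nearest library as a share of the group's range, with the CPM there and in the others, was 0.953 for Nampt in Bmal1WT replicate 1 (39.3 against 42.2 to 42.3) and 0.901 for Trim12a in Bmal1WT replicate 4 (14.8 against 21.6 to 22.3). In Bmal1cKO replicate 2 it was 0.847 for Frem2 (109 against 102 to 103), 0.925 for Arsi (1.34 against 0.898 to 0.931), 0.897 for Cdc25b (26.4 against 23 to 23.4) and 0.885 for Ifit1 (0.953 against 0.373 to 0.44). In Bmal1WT replicate 2 it was 0.838 for Ccdc80 (3.64 against 0.375 to 0.904) and 0.888 for Oas3 (9.59 against 0.804 to 1.79). Bmal1WT replicate 3 gave 0.854 for Ccl20 (1.72 against 0.728 to 0.872) and 0.858 for Rrm2 (17.5 against 19.9 to 20.3). The gap was 0.911 for Krt33a in Bmal1cKO replicate 1 (0.362 against 0.18 to 0.196), 0.841 for Hbb-bt in Bmal1cKO replicate 3 (0.645 against 0.258 to 0.319), 0.903 for Dcn in Bmal1WT replicate 4 (5.29 against 0.513 to 0.974) and 0.921 for Col1a1 in Bmal1cKO replicate 4 (3.7 against 0.75 to 0.982).

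Among list scores the gap was 0.957 for G2 and M phase genes in Bmal1WT replicate 1 (-0.156 against 0.0485 to 0.0577) and 0.917 for NRF2 and antioxidant genes in Bmal1WT replicate 2 (0.0823 against -0.0337 to -0.0241). It was 0.892 for TGF-beta and BMP targets in Bmal1WT replicate 4 (0.353 against -0.144 to -0.09), 0.944 for epidermal T cell markers in Bmal1WT replicate 2 (-0.792 against 0.243 to 0.304) and 0.933 for muscle, adipocyte and red cell markers in Bmal1cKO replicate 3 (-0.222 against -0.771 to -0.734).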

How the results depend on the processing

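The fits on female or male libraries alone and the count without the genes within 40 Mb of Bmal1 were chosen after the data were seen. The 34 called genes kept their sign wherever they were tested. Over 21 alternatives, 174 genes chosen by the rule or called gave 3630 comparisons. Of these 3472 had the outcome of the main fit, called or not called, 119 lost a call, 39 gained one and 0 reversed. The outcome was the same throughout for 129 genes. The 33 lists gave 627 comparisons, of which 547 had the outcome of the main fit, 46 lost a call, 33 gained one and 1 reversed. The outcome was the same throughout for 9 lists, and these were called in no fit, since estimated correlations called 0 lists. Outcomes that stayed the same thus include many results that were never called. The median of all genes moved by at most 0.008 on the log2 scale. In the simulation with a sex effect the genotype-only fit recovered 18.5% of changes of a log2 of 0.5 and 84.6% of those of 2, against 41.5% and 98.5% with sex as a covariate. That sex effect was invented and added to a spread estimated without sex in the model. The loss was thus built in, and it does not measure how many changes the genotype-only fit missed in the data.

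With the replicate block 152 genes were called (102 higher, 50 lower), among them all 34. It ended the list calls of the positive limb (adjusted p 0.0583) and of glycolysis (0.0521) and added Langerhans cells (0.00685) and T cells (0.00241, both 0.722 with the block and an estimated correlation), and changed no other list. The Bmal1 transcript passed with it at a log2 fold change of -0.47. Sex as a covariate called 119 genes (81 and 38), let Bmal1 pass (-0.47) and added the Langerhans and T cell lists (0.0364 each, 0.899 with an estimated correlation). The biological coefficient of variation was 0.159 without and 0.12 with this covariate, and the cause was not tested further.

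Without a count filter 71 genes were called (45 and 26) of 34070 tested, and Bmal1 passed at -0.46. DESeq2 called 252 (167 and 85), with Bmal1 at -0.46, and voom with quality weights 47 (29 higher), with Bmal1 at -0.48. Robust dispersions called 27 genes higher. An adjusted p under 0.01 left 21 genes, and leaving out the window around Bmal1, with p values adjusted again over the remaining genes, left 10 lower. Voom lost 6 of the 34, among them Atp6v1g3 (adjusted p 0.0915), Trim34a (0.0629) and Trim30d (0.0754). Female libraries alone called 13 genes (4 and 9) and male libraries alone 101 (77 higher), 12 and 21 of them shared with the 34. These 2 fits held the same number of libraries, so sample number does not account for the difference between them. The cause of these differences was not tested.

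Estimated correlations called 0 lists, with adjusted p 0.396 for the positive limb, 0.313 for YAP/TAZ, 0.689 for NF-kB, 0.907 for interferon, 0.313 for basal, 0.447 for differentiation, 0.632 for S phase, 0.941 for glycolysis, 0.726 for barrier lipids, 0.447 for muscle, adipocyte and red cells and 0.822 for growing hair. Fry called 2 lists and gave 0.063 for YAP/TAZ, 0.371 for NF-kB, 0.767 for interferon, 0.201 for differentiation, 0.315 for S phase, 0.947 for glycolysis, 0.371 for barrier lipids, 0.126 for muscle, adipocyte and red cells and 0.732 for growing hair. The T cell list passed with DESeq2 size factors (0.0392), library size only (0.0428) and no filter (0.0417). The muscle, adipocyte and red cell list missed with no filter (0.37) and the CPM filter (0.23), and the growing hair list with the CPM filter (0.135). The cause was not tested.

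In female libraries alone 6 lists were called. E-box targets passed (0.02), and calls were lost for the positive limb (0.0948), YAP/TAZ (0.0733), NF-kB (0.196), interferon (0.0948), glycolysis (0.0507), muscle, adipocyte and red cells (0.0948) and growing hair (0.174). Cholesterol synthesis reversed and was called lower (0.000212). In male libraries alone the positive limb (0.136), YAP/TAZ (0.144) and glycolysis (0.261) lost their call. AP-1 (0.0016), G2 and M phase (0.000814), cholesterol synthesis (0.000593, higher), immediate-early (0.0382), Langerhans (0.0179), T cell (0.023) and sebaceous lists (0.0337) gained one. Both fits held fewer libraries than the main fit, and the cause of the lost and gained calls was not tested.

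Leaving out 1 library gave 11 genes higher (without Bmal1cKO replicate 2) to 18 and 11 lower (without Bmal1cKO replicate 1) to 15. The adjusted p of lists ran from 0.0182 to 0.378 for E-box targets, 0.00557 to 0.0831 for the positive limb, 0.0025 to 0.882 for AP-1, 0.000289 to 0.0539 for NF-kB, 9.08e-08 to 0.238 for interferon, 3.01e-05 to 0.643 for glycolysis and 2.37e-05 to 0.0539 for barrier lipids. It ran from 0.0033 to 0.0514 for muscle, adipocyte and red cells, 8e-06 to 0.0804 for growing hair, 0.0046 to 0.897 for Langerhans cells and 2.4e-06 to 0.617 for T cells. Lists gained a call without Bmal1WT replicate 1 (stress keratins, 0.028 to 0.836, oxidative phosphorylation, 0.028 to 0.974), without Bmal1WT replicate 4 (endothelial, 0.0382 to 0.92, bulge, 0.0303 to 0.989) and without Bmal1cKO replicate 4 (melanocytes, 0.00291 to 0.866). Without Bmal1cKO replicate 3 G2 and M phase (0.00542 to 0.855), cholesterol synthesis (0.0418 to 0.998) and sebaceous lists (0.0418 to 1) gained one. Immediate-early genes (0.00294 to 0.838) passed without Bmal1cKO replicate 1 and without Bmal1WT replicate 4 (0.0474). The cause was not tested.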

Other observations

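The genes in this part were chosen after their values were seen. Aldh4a1, a mitochondrial enzyme of proline breakdown, fell from 62.4 ± 2.94 to 44.9 ± 1.79 CPM (SD, n = 4, log2 fold change -0.48 ± 0.05 SE, edgeR quasi-likelihood adjusted p = 0.00586) and was called in all 8 left-out fits. It overlaps Gm21969 on the same strand (26834 counts against 17549 of Aldh4a1), so its counts are uncertain. Mmp14, a membrane-bound matrix protease gene, rose by 0.35 ± 0.05 on the log2 scale (edgeR adjusted p = 0.022) but was called in the left-out fits only without Bmal1WT replicate 2 (0.0299) or Bmal1cKO replicate 4 (0.0326), with an adjusted p of up to 0.101 otherwise. The processed pseudogene Gm44075 on chromosome 6 had 0 counts in Bmal1WT and 89 in Bmal1cKO (0.591 CPM), at least 34-fold higher against a floor of 3 counts over the group.

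Several genes that missed the threshold in the genotype-only fit passed with the replicate block. Cxcl14, a chemokine gene of keratinocytes, was at 307 ± 129 CPM in Bmal1WT and 693 ± 148 CPM in Bmal1cKO (SD, n = 4, 1.17 ± 0.29, edgeR adjusted p = 0.246, 0.00633 with the block). The RNA-binding protein gene Igf2bp2 was at 1.8 and 6.52 CPM (1.86 ± 0.31, edgeR adjusted p = 0.0608, 0.00194 with the block), and the imprinted noncoding RNA H19 at 0.701 and 5.41 CPM (2.94 ± 0.71, 0.23, 0.00108 with the block). For H19 the groups overlapped, with Bmal1cKO replicate 4 at 1.091 CPM against 0.287 to 1.099 CPM in Bmal1WT. Its call thus rests on the pairing by replicate number, which the labels do not state. Clspn, which encodes a replication checkpoint protein, was at 9.55 and 16.8 CPM (0.82 ± 0.17, edgeR adjusted p = 0.15, 0.0273 with the block).

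Sex itself, tested with genotype in the same fit, had 361 genes past an edgeR adjusted p under 0.05, of which 129 were higher and 232 lower in male libraries. That exceeds the 119 genes called for genotype in the same fit.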
